A study of Mus musculus with 36 samples.

How the data were processed

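The series held 36 mouse samples, of which the 20 RNA-seq libraries were analysed and the 15 ChIP-seq samples and 1 ATAC-seq sample were not analysed here. Per the labels, the RNA-seq libraries came from 3 culture systems: 4 from organoids of pancreatic epithelial cells, 8 from the KSIC_806 pancreatic ductal adenocarcinoma (PDA) line, and 8 from E14 mouse embryonic stem cells and the embryoid bodies (EBs) made from them. The labels of the PDA libraries also carry the mark S4, and its meaning, which bears on how the WT response to TGFβ is read, is not given in the sources used here. Per the labels' protocols, total RNA with an integrity number above 9.5 was made into libraries with the TruSeq RNA Sample Prep Kit v2, a kit that does not mark strand, and sequenced as single-end reads.

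The deposited signal was 1 normalized read count per gene and library, in 3 tables, one for each culture system. The submitters' processing notes name FastQC 0.11.5, Bowtie2, HTSeq 0.6.1p1, DESeq2 3.4 and HOMER with the mm10 genome build, without giving the role or the order of these tools for each data type. The deposited values carried decimals. In each library, dividing them by the smallest common step gave whole numbers for 100% of values (tolerance 0.001), so every value was a whole read count divided by 1 factor per library. These recovered reads gave the depth of each library, the counting intervals and the alternatives that need counts. The tables held 18758 genes for the organoids, 18256 for the PDA cells and 19834 for the EBs. None held a mitochondrial gene, and 25 organoid and 27 EB genes carried names that a spreadsheet had turned into dates; these were kept as tested genes and are not named.

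Replicated tables were filtered to genes with a deposited value of at least 10 in at least 2 of the 8 libraries, which left 13226 genes in the PDA table and 15227 in the EB table. Organoid genes needed a mean of at least 10 over the 4 libraries, which left 13443. Values were transformed as log2(value + 1). For each replicated table, limma (version 3.58.1, in R 4.3.3) was fitted with the trend option over all 8 libraries in 4 groups of 2, so that the groups shared an estimate of the spread. P-values from limma were two-sided and adjusted over the genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. The PDA contrasts were TGFβ against the receptor inhibitor in each genotype, the difference between these responses (the interaction), their mean, and KO against WT under each treatment. The EB contrasts were day 4 against day 0 in each genotype, the interaction, and KO against WT on each day.

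Gene lists, 34 in all, were written before the data were examined. A list with at least 5 tested genes was tested with camera from limma at its preset correlation of 0.01, adjusted over the lists of a contrast, and tested again with a correlation estimated from the data. List members past the threshold were counted after adjustment over all genes and again adjusted over the list alone. Lists made of genes that the study is known to discuss are not independent evidence and are marked where they appear. A further 5 lists were written after the data were seen. They appear among the closing observations and, marked as added, in the organoid results. Over the genes called in the mean TGFβ response, fry from limma tested whether the interaction ran with or against the response.

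The organoid table had 1 library per condition. Its contrasts were log2 ratios of value + 1 with exact 95% counting intervals from the recovered reads, without p-values, and a list's median is given as a percentile among 10000 random lists of the same size matched on mean expression. Counting intervals and detection floors cover counting error only. The interval of a list or chromosome median covers the spread between its genes. The percentiles come from random genes, so they leave out correlation between the genes of a list. The floor for a gene at 0 was 3 counts over the group, which equals a value of 1.3 to 1.89 in the PDA groups and 1.35 to 1.64 in the EB groups. Folds against a group at 0 are lower bounds at this floor.

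The genes to be named were set by a rule made before the data were examined. For each contrast these were Rreb1, the 6 largest positive and 6 largest negative log2 fold changes among genes past the threshold with a mean of at least 50 and groups that did not overlap, and up to 4 members per list with the smallest adjusted p. Snai1, Has2 and Smad7 in the PDA and organoid tables and T, Eomes, Gsc and Mixl1 in the EB table were always given. In the organoid table the rule took the 6 largest ratios in each direction among genes of at least 50 in the higher library, and up to 4 list members by size. Some genes that these rules took are not reported here. Genes outside this rule are said to be chosen after their values were seen. Gene positions came from the GRCm38.p6 annotation of the mm10 build.

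The pipeline was tested on simulated counts with 50 genes changed at each of 4 fold sizes. For the TGFβ response in WT, run on 13058 genes, it recovered 34 of the genes changed 1.5-fold, 47 of those changed 2-fold and all 50 at 4-fold and at 8-fold, and it called 14 of 12838 unchanged genes. For the day 4 change in WT EBs, run on 14946 genes, the numbers were 38, 48, 50 and 50, with 12 of 14726 unchanged genes called. In the simulation every group had the same spread for a gene, and few genes changed. The real PDA replicates differed unequally (chi-square per degree of freedom 1.94 in WT TGFβ and 48.5 in WT SB). The rates of false calls therefore need not carry over to the real counts of called genes.

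Alternatives chosen before the data were examined were pseudocounts of 0.25 and 8, no filter, a mean of at least 100, quantile normalization, rescaling to the same total, the replicate number as a block, robust moderation, a fit of only the groups compared, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. On those reads edgeR called 5171 genes for the TGFβ response in WT, 5053 in KO and 2818 for the interaction. For the organoids the alternatives were both pseudocounts, a mean of at least 50 and centring on the median. Leaving out X-linked and Y-linked genes from the EB table, and airway and lung macrophage genes from the organoid table, was chosen after seeing the data.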

Results

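Gene expression was measured by RNA-seq in 20 mouse libraries from 3 culture systems, to follow how cells labelled WT or KO for Rreb1, a zinc finger transcription factor gene, respond to TGFβ and how they differentiate. KSIC_806 PDA cells with either label were treated with SB505124, an inhibitor of the TGFβ type I receptor (2.5 µM, 6 h), or with TGFβ (100 pM, 1.5 h), with 2 libraries in each of the 4 groups. E14 embryonic stem cells labelled WT or KO were sampled at day 0 and as embryoid bodies at day 4, also with 2 libraries in each of 4 groups. Pancreatic epithelial organoids, with and without doxycycline (dox, 1 µg/mL from plating), received the same SB505124 or TGFβ treatment, with 1 library per condition. Recovered depth ran from 38.73 to 44.5 M reads in 7 PDA libraries and was 20.41 M in KO SB replicate 1. It ran from 19.89 to 29.08 M reads in the EBs and from 23.91 to 35.81 M in the organoids. The first principal component of the PDA libraries, with 69.4% of the variance, separated the genotypes, and the second, with 19.6%, the treatments. SB505124 and TGFβ were given for different times, so each TGFβ comparison carries both the ligand and the time. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples. Nor do they give separate lines or clones within a genotype. KO against WT differences and interactions therefore cannot be told apart from other differences between the lines used. Levels are deposited values, given as mean ± SD of 2 libraries (n = 2 per group).

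The targeted gene, Rreb1 (chromosome 13, 37778382 to 37952005), was read first because it checks the genotype labels. Its transcript did not fall to background in any library labelled KO. In PDA cells its level was 1458 and 1501 in the WT SB libraries, 4293 and 4212 in WT TGFβ, 2164 and 2195 in KO SB, and 2886 and 2560 in KO TGFβ. Under SB505124 the transcript was higher in the cells labelled KO (log2 fold change 0.56 ± 0.08 SE, adjusted p = 0.000564), and under TGFβ it was lower (−0.65 ± 0.08, adjusted p = 0.000364). In EBs the level was 1085 and 1019 in WT at day 0, 1482 and 1586 in WT at day 4, 2642 and 2830 in KO at day 0, and 1920 and 1512 in KO at day 4. It was higher in the cells labelled KO at day 0 (1.38 ± 0.10, adjusted p = 2.35e-08). At day 4 the difference did not pass the threshold (0.15 ± 0.10, adjusted p = 0.198), although without KO day 4 replicate 2 it did (0.32, adjusted p = 0.00506). The organoid libraries held 2078 without dox under SB505124, 2235 without dox under TGFβ, 1657 with dox under SB505124 and 2297 with dox under TGFβ. A gene-level count does not show a small edit, so these values neither bear out nor exclude the label, and the groups are called "labelled KO" or KO for the label alone.

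**Figure D1:**
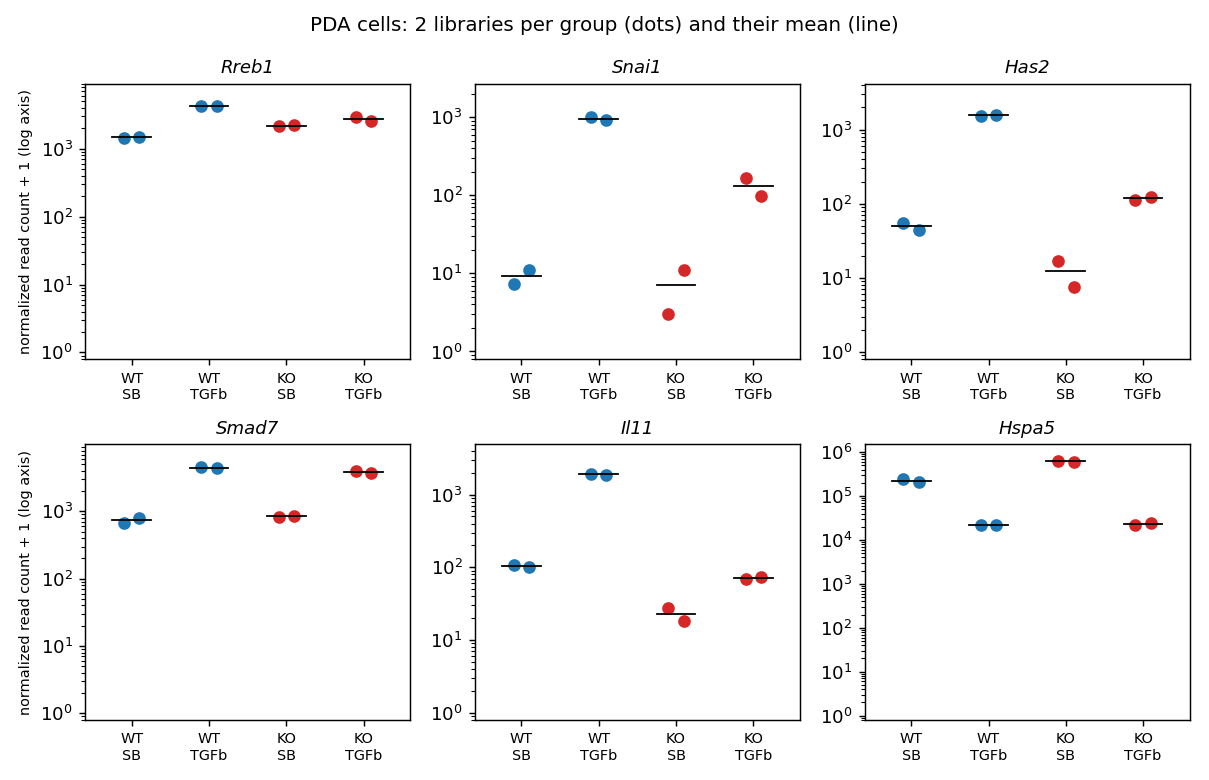
Deposited normalized counts plus 1 (log axis) of 6 genes in the 8 PDA libraries, with 1 dot per library, blue for WT and red for labelled KO, and a black line at the mean of each group. Snai1, Has2 and Il11 reached 963, 1564 and 1899 under TGFβ in WT and 130, 118 and 70.8 in the cells labelled KO, while Smad7 reached 4449 and 3849.

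In WT PDA cells, TGFβ raised the EMT transcription factor gene Snai1 from 8.23 ± 2.55 to 963 ± 65.5 (log2 fold change 6.73 ± 0.57 SE, adjusted p = 0.000121). The hyaluronan synthase gene Has2 rose from 48.5 ± 6.68 to 1564 ± 57.5 (4.99 ± 0.34, adjusted p = 4.73e-05). The SMAD feedback inhibitor gene Smad7 rose from 734 ± 76.3 to 4449 ± 85.7 (2.60 ± 0.09, adjusted p = 2.55e-06). Among the largest increases were Cldn4, encoding a tight junction protein, from 3.20 ± 0.661 to 819 ± 36.0, the activity-regulated gene Arc, from 15.1 ± 1.87 to 791 ± 14.5, and the scavenger receptor gene Olr1, from 9.16 to 265. The direct SMAD target Skil rose from 1290 ± 127 to 13040 ± 394. The profibrotic cytokine gene Il11 rose from 103 ± 4.98 to 1899 ± 57.6 and the fibronectin gene Fn1 from 12340 ± 15.2 to 25600 ± 361. The chemokine gene Ccl20 was among the largest falls, from 1129 ± 52.9 to 12.5 ± 2.00 (−6.39 ± 0.14, adjusted p = 7.84e-07). The collagenase gene Mmp13 fell from 23990 ± 3630 to 1304 ± 43.8, the stress gene Ddit3 from 1832 ± 286 to 154 ± 24.3, and Myc from 9585 ± 995 to 1322 ± 11.5.

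Of 22 TGFβ/SMAD feedback and direct target genes, 18 rose and 1 fell under TGFβ in WT, with the same counts adjusted over the list alone (median log2 fold change 1.54, camera adjusted p = 1.49e-10). This call held with an estimated correlation (adjusted p = 0.0301), and no other list call in the WT response did (adjusted p from 0.11 to 0.224). Among 18 fibrogenic factors and matrix genes, 13 rose and 4 fell, again with the same counts adjusted over the list alone (median 1.03, adjusted p = 0.000309, and 0.11 with an estimated correlation). That list was drawn from genes the study discusses, so its count is not independent evidence. Epithelial junction and keratin genes rose in 11 of 19 cases and fell in 1, Dsp among the former (7348 ± 157 to 18600 ± 16.0), also adjusted over the list alone (median 0.527, adjusted p = 0.000441). Mesenchymal markers rose in 7 of 13 and fell in 1, also adjusted over the list alone (median 0.524, adjusted p = 0.0105). ERK pathway output genes fell in 12 of 20 cases and rose in 1 (adjusted over the list alone, 13 and 2, median −0.411, adjusted p = 0.000297). Spry2 went from 1750 ± 13.6 to 460 ± 23.8 and Dusp6 from 6000 ± 75.1 to 2078 ± 50.6. Cell cycle genes rose in 11 of 23 cases and fell in 1, also when adjusted over the list alone (median 0.26, adjusted p = 0.00332). Cholesterol synthesis genes fell in 7 of 19 and rose in 1 (adjusted over the list alone, 8 and 1, median −0.284, adjusted p = 0.0214). Quantile normalization ended this last call (adjusted p = 0.0608). The 9 EMT transcription factors did not move as a list (median 0.189, adjusted p = 0.798), with 3 higher and 2 lower, or 4 and 2 adjusted over the list alone, and this list too came from the study. In all, limma called 4887 of 13226 genes, 2565 higher and 2322 lower. The balance turned after quantile normalization (2352 and 2716) and not after rescaling to the same total (2825 and 1980). Without WT TGFβ replicate 1 the count was 2254 and without replicate 2 it was 2286.

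In the PDA cells labelled KO, TGFβ raised Snai1 from 6.05 ± 5.72 to 130 ± 47.8 (log2 fold change 4.46 ± 0.57 SE, adjusted p = 0.000802). Has2 rose from 11.3 ± 6.84 to 118 ± 8.61 (3.39 ± 0.34, adjusted p = 0.000267), and Smad7 from 845 ± 31.5 to 3849 ± 179 (2.19 ± 0.09, adjusted p = 4.09e-06). Cldn4 went from 0 to 82.6 ± 13.9, at least 43.7-fold higher, and Fam167a from 0 to 27.7 ± 5.71, at least 14.6-fold higher. The endothelin gene Edn2 rose from 49.2 ± 7.00 to 1000 ± 135 and the WNT ligand gene Wnt9a from 19.6 ± 2.12 to 295 ± 41.1. Ccl20 fell from 4460 ± 99.2 to 60.4 ± 5.64 (−6.19 ± 0.14, adjusted p = 3.24e-07), and Mmp13 from 28890 ± 964 to 548 ± 69.3. Ddit3 fell from 5595 ± 166 to 146 ± 0.332 and Rgs16, which encodes a brake on G protein signalling, from 1071 ± 58.3 to 16.3 ± 2.60. Rreb1 itself rose in the cells labelled KO (0.32 ± 0.08, adjusted p = 0.0133), but not without KO SB replicate 1 (adjusted p = 0.0874), KO SB replicate 2 (0.0715) or KO TGFβ replicate 1 (0.0622).

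TGFβ/SMAD targets rose in 14 of 22 cases and fell in 3 in the cells labelled KO, also adjusted over the list alone (median 1.08, camera adjusted p = 6.32e-06, and 0.0778 with an estimated correlation). Cell cycle genes rose in 22 of 23 cases with none falling, the same adjusted over the list alone (median 0.628, adjusted p = 3.47e-10, and 0.0778 with an estimated correlation). The cyclin gene Ccne1 went from 710 ± 14.0 to 2058 ± 141 and Mcm7, a replication licensing gene, from 7652 ± 22.0 to 13690 ± 155. ERK output genes fell in 15 of 20 cases and rose in 2 by either adjustment, so also adjusted over the list alone (median −0.934, adjusted p = 7.87e-07), Egr1 from 380 ± 8.00 to 47.7 ± 3.32 among them. Epithelial genes rose in 8 of 19 cases and fell in none, also adjusted over the list alone (median 0.316, adjusted p = 0.00768). Cholesterol synthesis genes rose in 9 of 19 and fell in 1 (adjusted over the list alone, 10 and 1, median 0.296, adjusted p = 0.00368), Dhcr7 from 709 ± 1.09 to 1357 ± 16.6. No list call in this comparison held with an estimated correlation (adjusted p from 0.0778 to 0.158). Of the lists drawn from the study, which are not independent evidence, the EMT transcription factors did not move as a list (1 higher and 4 lower of 9, also adjusted over the list alone, median −0.409, adjusted p = 0.145). The fibrogenic genes did not either (9 higher and 5 lower of 18, also adjusted over the list alone, median 0.448, adjusted p = 0.503). With edgeR more called genes were lower than higher (2406 higher and 2647 lower). In the main fit, 5113 genes were called, 2731 higher and 2382 lower, or 3830 and 1802 after rescaling the libraries to the same total, which shifted the median of all genes by 0.11 on the log2 scale. The count was 2956 without KO SB replicate 1 and 3148 without KO SB replicate 2.

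The difference between the responses of the genotypes was tested directly as an interaction, which asks which TGFβ changes differ in the cells labelled KO. The difference, KO minus WT on the log2 scale, was −2.28 ± 0.80 for Snai1 (adjusted p = 0.0805), −1.59 ± 0.49 for Has2 (adjusted p = 0.0537) and −0.42 ± 0.13 for Smad7 (adjusted p = 0.0526), none past the threshold. Arc rose in WT but stood at 15.0 ± 9.88 under SB505124 and 14.1 ± 4.46 under TGFβ in the cells labelled KO (interaction −5.60 ± 0.60, adjusted p = 0.00158). The cytokine feedback gene Cish rose from 27.9 ± 9.58 to 449 ± 24.1 in WT and stood at 30.1 ± 2.80 and 49.9 ± 7.59 in KO (−3.30 ± 0.35, adjusted p = 0.00157). Lancl3 stood at 462 ± 64.2 and 311 ± 18.8 in WT and fell from 647 ± 57.5 to 19.97 ± 0.0453 in KO (−4.38 ± 0.19, adjusted p = 0.000179). The mitochondrial folate enzyme gene Aldh1l2 fell from 394 ± 28.9 to 115 ± 5.54 in WT and from 181 ± 48.4 to 4.08 ± 0.633 in KO (−3.37 ± 0.30, adjusted p = 0.000928). In the other direction, Rgs2 fell less in KO (271 ± 14.8 to 129 ± 11.8) than in WT (181 ± 9.86 to 21.8 ± 0.640, interaction 1.93 ± 0.19, adjusted p = 0.00148). Rreb1 itself responded less in KO (−1.20 ± 0.11, adjusted p = 0.000933).

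As lists, TGFβ/SMAD targets responded less in the cells labelled KO (median interaction −0.573, 10 of 22 lower and 3 higher, 12 and 3 adjusted over the list alone, camera adjusted p = 0.00365). Immediate early genes had a lower TGFβ change in KO (median −0.658, 8 of 17 lower and none higher, 10 and none adjusted over the list alone, adjusted p = 2.99e-05), with list medians of 0.233 in WT and −0.548 in KO. Fos, among them, went from 109 to 398 in WT and from 1145 to 544 in KO. From the study, and so not independent evidence, the fibrogenic genes had a lower change (median −0.743, 7 of 18 lower and 3 higher, 10 and 3 adjusted over the list alone, adjusted p = 0.00269), Vegfa and Fn1 among them, with list medians of 1.03 in WT and 0.448 in KO. The EMT transcription factors, also from the study and not independent evidence, also had a lower change (median −0.756, 4 of 9 lower and none higher, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0447), with list medians of 0.189 in WT and −0.409 in KO. Zeb2, among them, went from 456 to 639 in WT and from 412 to 200 in KO. The EMT call was lost without WT SB replicate 2 (adjusted p = 0.0799) or KO TGFβ replicate 1 (0.0513). Cell cycle genes (median 0.361, 12 of 23 higher and none lower, 13 and none adjusted over the list alone, adjusted p = 1.57e-06) rose more in KO. They started lower there, since under SB505124 the list was lower in KO than in WT. Ccne1 went from 1613 to 1725 in WT and from 710 to 2058 in KO, and Mcm7 from 11230 to 14630 and from 7652 to 13690. Cholesterol synthesis genes, which had fallen in WT (median −0.284) and risen in KO (0.296), had a higher change in KO (median interaction 0.479, 9 of 19 higher and none lower, 12 and none adjusted over the list alone, adjusted p = 1.89e-06). With an estimated correlation none of these calls held (adjusted p from 0.135 to 0.315). With the replicate number as a block the interaction was called for 1596 genes. In the main fit it was called for 2886 genes, 1284 higher and 1602 lower, or 1869 and 1388 after rescaling to the same total. The count fell to 764 without WT TGFβ replicate 1, 827 without WT TGFβ replicate 2, 940 without KO SB replicate 1 and 1188 without KO SB replicate 2. Of 2734 genes called in both genotypes, 2380 moved the same way and 354 in opposite directions.

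The mean of both responses was used to pick genes that differed between TGFβ and SB505124 without favouring a genotype. Such genes can include those moved by the inhibitor or by its longer time. The chaperone gene Hspa5 (chromosome 2, 34772090 to 34776529) was among the largest falls (−4.05 ± 0.07, adjusted p = 5.42e-08), from 223000 ± 25600 to 21670 ± 273 in WT and from 625600 ± 16500 to 23450 ± 1890 in KO. The SMAD targets Skil and Klf10 rose by 2.99 and 2.41 and Bhlhe40 by 2.51 on the log2 scale. TGFβ/SMAD targets rose in 17 of 22 cases and fell in 2, also adjusted over the list alone (median 1.17, camera adjusted p = 2.28e-08, and 0.0469 with an estimated correlation). Cell cycle genes rose in 19 of 23 cases and fell in none (21 and none adjusted over the list alone, median 0.49, adjusted p = 3.57e-08, and 0.0816 with an estimated correlation). Fibrogenic genes, from the study and not independent evidence, were also called (median 0.756), as were epithelial genes (0.377), mesenchymal markers (0.345) and ERK output genes (−0.802). None of these 4 calls held with an estimated correlation (adjusted p from 0.0816 to 0.147). With edgeR the called rises and falls numbered 2983 and 3016, and after quantile normalization 2960 and 2902. In the main fit, 5961 genes were called, of which 3213 rose and 2748 fell (4064 and 2124 after rescaling to the same total). Over them, the median response along the direction of the mean was 0.461 in WT and 0.508 in KO, larger in KO for 3199 genes and in WT for 2762, a difference called by fry. That difference changed with single libraries, since its sign turned without WT SB replicate 2 (−0.0163 against 0.047), and the call was lost without WT SB replicate 1 (0.0247) or KO TGFβ replicate 2 (0.0525). Among these genes 1748 passed the interaction test, with a response along that direction lower in KO for 777 and higher for 971.

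**Figure D2:**
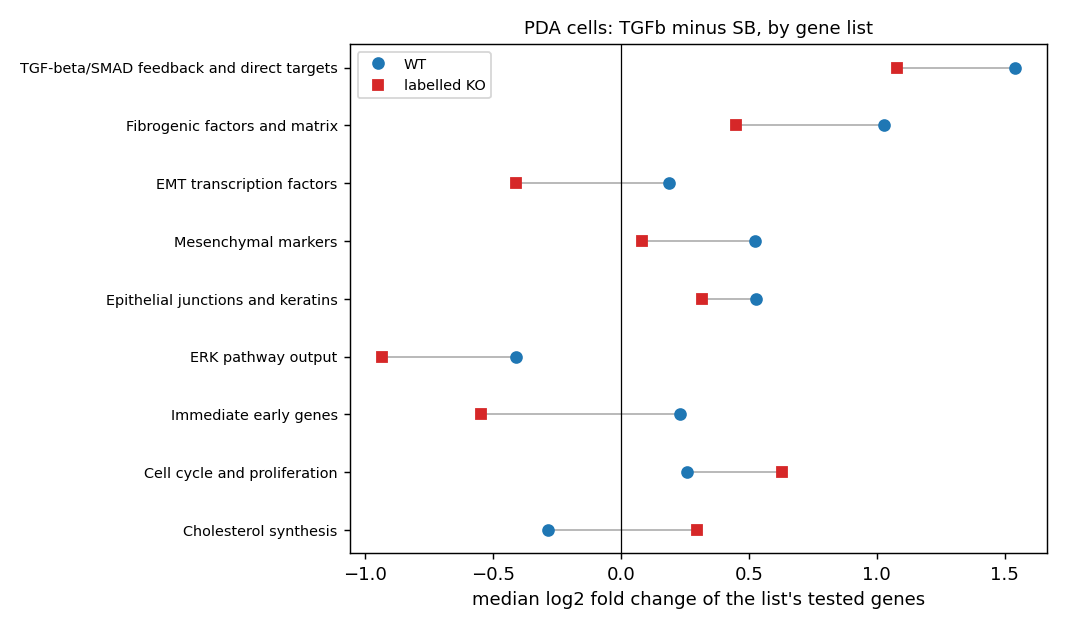
Median log2 fold change (x axis) of each gene list (y axis) for TGFβ against SB505124 in PDA cells, with blue circles for WT and red squares for labelled KO. TGFβ/SMAD targets lie at 1.54 in WT and 1.08 in KO, and cell cycle genes at 0.26 and 0.628.

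The PDA cells labelled KO were compared with WT with the TGFβ receptor inhibited. The gel-forming mucin gene Muc5ac was at 151 ± 10.4 in WT and 33440 ± 505 in KO (log2 fold change 7.79 ± 0.07 SE, adjusted p = 4.28e-09). The gastrokine gene Gkn2 stood at 9.61 ± 3.28 and 3510 ± 50.6 (8.40 ± 0.20, adjusted p = 3.27e-07). The carboxylesterase genes Ces1g (1.37 against 802) and Ces1d (0 against 227) were also higher in KO, but this family shares reads, so the member is uncertain. Prl, the prolactin gene, was at 3372 ± 487 in WT and 0 in KO, at least 1780-fold lower. The surface protein gene Cdcp1 (553 ± 14.1), the kinase genes Lrrk2 (317 ± 35.0) and Syk (293 ± 6.47) and the nuclear receptor gene Nr2f1 (250 ± 15.1) were expressed in WT and at 0 in KO. They were at least 292-, 167-, 155- and 132-fold lower. Has2 was lower in KO (−2.13 ± 0.34, adjusted p = 0.00137), while Snai1 (−0.65 ± 0.57, adjusted p = 0.361) and Smad7 (0.21 ± 0.09, adjusted p = 0.0828) did not pass the threshold.

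Immediate early genes were higher in the cells labelled KO in 11 of 17 cases and lower in none, the same adjusted over the list alone (median 0.817, camera adjusted p = 0.000943). Fos stood at 109 ± 7.28 in WT and 1145 ± 10.3 in KO. ERK output genes were higher in 14 of 20 cases and lower in 2 (adjusted over the list alone, 15 and 2, median 0.543, adjusted p = 0.0034), Dusp4 at 2055 ± 81.5 and 7087 ± 266. Cell cycle genes were lower in 12 of 23 cases and higher in none by either adjustment, that is also adjusted over the list alone (median −0.271, adjusted p = 0.00684). Ccne1 stood at 1613 ± 4.50 and 710 ± 14.0. WNT/β-catenin targets were lower in 6 of 8 cases and higher in 1, also adjusted over the list alone (median −1.80, adjusted p = 0.0113, and 0.0811 with a mean of at least 100). Among them Tcf7 stood at 273 ± 3.32 and 30.5 ± 6.17 and Apcdd1 at 6954 ± 320 and 1888 ± 33.3. From the study, and not independent evidence, EMT transcription factors were lower in 5 of 9 cases and higher in none, also adjusted over the list alone (median −0.647, adjusted p = 0.0138, and 0.135 with a mean of at least 100). Prrx1 stood at 137 ± 9.02 and 0, at least 72.4-fold lower, and Twist2 at 151 ± 14.2 and 13.6 ± 3.59. The study's list of SOX4, KLF5 and apoptosis genes, with the same limit, was higher in 10 of 14 cases and lower in none, also adjusted over the list alone (median 0.423, adjusted p = 0.00684). Klf5 stood at 1993 ± 83.0 and 3055 ± 25.6. Glycolysis genes were higher in 9 of 18 cases and lower in 2, also adjusted over the list alone (median 0.247, adjusted p = 0.0383). This call was lost with a mean of at least 100 (0.0811), with quantile normalization (0.0643) and without WT SB replicate 1 (0.0882) or KO SB replicate 2 (0.0868). With an estimated correlation none of these list calls held (adjusted p from 0.305 to 0.323). The count was 7428 genes, 3828 higher and 3600 lower, or 2975 and 4901 after rescaling to the same total, which shifted the median of all genes by −0.15.

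Under TGFβ, Snai1 was lower in the PDA cells labelled KO than in WT (−2.93 ± 0.57, adjusted p = 0.00483). Has2 was lower too (−3.72 ± 0.34, adjusted p = 0.000103), while Smad7 was not called (−0.21 ± 0.09, adjusted p = 0.0997). Il11 stood at 1899 ± 57.6 in WT and 70.8 ± 2.73 in KO, Vegfa at 12030 ± 152 and 3449 ± 316 and Fn1 at 25600 ± 361 and 9636 ± 154. All 3 were lower in KO. Among EMT transcription factor genes, Zeb2 was at 639 ± 6.61 and 200 ± 2.38 and Twist2 at 130 ± 10.5 and 9.53 ± 1.95. Gkn2 (23.1 ± 1.37 and 5369 ± 488) and the complement gene C9 (5.49 and 1945) were again higher in KO and Prl again lower (1745 ± 59.5 and 0, at least 1280-fold).

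EMT transcription factors were lower in all 9 cases (median −1.67, camera adjusted p = 1.06e-05). Fibrogenic genes were lower in 13 of 18 and higher in 3 (median −1.10, adjusted p = 0.000284). Both lists came from the study and are not independent evidence, and both counts were the same adjusted over the list alone. TGFβ/SMAD targets were lower in 10 of 22 cases and higher in 2, also adjusted over the list alone (median −0.316, adjusted p = 0.0346). Mesenchymal markers were lower in 7 of 13 and higher in 2, likewise (median −0.306, adjusted p = 0.0346, and 0.0524 after rescaling to the same total). WNT targets were lower in 6 of 8 and higher in none, likewise (median −1.83, adjusted p = 0.000883). Cholesterol synthesis genes were higher in 14 of 19 cases and lower in none (adjusted over the list alone, 15 and none, median 0.68, adjusted p = 1.06e-05), Lss at 1827 ± 3.87 and 4084 ± 118 among them. YAP/TEAD targets were higher in 10 of 12 and lower in 1, also adjusted over the list alone (median 0.474, adjusted p = 0.000883). Among them, Ankrd1 stood at 1677 ± 55.1 and 3713 ± 196. ERK output genes were higher in 10 of 20 and lower in 2 (adjusted over the list alone, 13 and 3, median 0.31, adjusted p = 0.0346). The study's SOX4, KLF5 and apoptosis genes, not independent evidence, were higher in 8 of 14 and lower in 2, also adjusted over the list alone (median 0.288, adjusted p = 0.0346). Without KO TGFβ replicate 1 neither the ERK nor the SOX4 call held (adjusted p = 0.113 and 0.0815), and the latter was also lost with no filter (0.0696). Interferon response genes were higher in 6 of 14 and lower in none (adjusted over the list alone, 7 and none, median 0.462, adjusted p = 0.0414), with Mx1 at 10.1 ± 1.48 and 201 ± 28.1. That call was lost with a mean of at least 100 (0.715), a pseudocount of 0.25 (0.0511), and without WT TGFβ replicate 2 (0.0613), KO TGFβ replicate 1 (0.0786) or KO TGFβ replicate 2 (0.0565). No list call here held with an estimated correlation (adjusted p from 0.108 to 0.367). In all 5316 genes were called, 2808 higher and 2508 lower (2360 and 3305 after rescaling to the same total), with 3212 without WT TGFβ replicate 1 and 3266 without WT TGFβ replicate 2.

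Differentiation was followed from embryonic stem cells at day 0 to embryoid bodies at day 4. In WT, the mesoderm gene T (chromosome 17, 8434423 to 8442496) rose from 7.71 ± 1.08 to 1277 ± 522 (log2 fold change 7.14 ± 0.29 SE, adjusted p = 8.03e-11). Eomes, which acts in the primitive streak, rose from 101 ± 18.8 to 2585 ± 905 (4.64 ± 0.18, adjusted p = 6.53e-11). Mixl1 rose from 3.09 ± 2.65 to 825 ± 438 (7.72 ± 0.44, adjusted p = 2.66e-09), and the organizer gene Gsc from 12.4 ± 2.11 to 64.8 ± 4.64 (2.30 ± 0.52, adjusted p = 0.0014). The fetal liver and yolk sac gene Afp went from 0 to 1517 ± 340, at least 927-fold higher, and the apelin receptor gene Aplnr from 0 to 1483 ± 600, at least 906-fold higher. Hand1, a regulator of early mesoderm, rose from 4.41 ± 0.620 to 4299 ± 1360, Kdr, a receptor gene of blood vessel precursors, from 29.3 ± 2.05 to 2759 ± 1220, and Snai1 from 37.1 ± 0.592 to 515 ± 142. Inhbb was among the largest falls, from 1146 ± 32.5 to 30.2 ± 6.05 (−5.21 ± 0.14, adjusted p = 2.19e-12). The naive pluripotency genes Klf4 and Esrrb fell from 5925 ± 132 to 618 ± 12.9 and from 22170 ± 505 to 4110 ± 110.

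Naive pluripotency genes fell in 18 of 20 cases and rose in 1, and primitive and visceral endoderm genes rose in 21 of 22 and fell in none, both also adjusted over the list alone (medians −1.74 and 3.07, camera adjusted p = 1.34e-12 and 1.45e-11). Both calls held with an estimated correlation (adjusted p = 0.0496 for each), and the other list calls in this comparison did not (adjusted p from 0.1 to 0.507). Primitive streak and mesendoderm genes rose in 20 of 22 cases and fell in 2 (median 4.61, adjusted p = 7.94e-08). EMT transcription factors rose in 9 of 10 and fell in none (median 3.76, adjusted p = 6.62e-05). Both lists came from the study and are not independent evidence, and the counts were the same adjusted over the list alone. Mesoderm genes rose in 21 of 22 and fell in 1, also adjusted over the list alone (median 3.55, adjusted p = 2.54e-08). BMP/ID targets rose in 13 of 14 and fell in none (14 and none adjusted over the list alone, median 2.12, adjusted p = 1.01e-06), with Id3 going from 174 ± 12.6 to 1856 ± 91.1. Definitive endoderm genes rose in 12 of 14 and fell in none (13 and none adjusted over the list alone, median 2.42, adjusted p = 2.83e-06). Hox genes rose in 13 of 15 with none falling, also adjusted over the list alone (median 4.13, or 4.04 with genes at 0 set to their bound, adjusted p = 6.62e-05). Formative pluripotency genes rose in 12 of 14 and fell in 1, also adjusted over the list alone (median 0.722, adjusted p = 1.47e-05), Fgf5 from 29.1 ± 10.3 to 2608 ± 325. Also called were epithelial junction and keratin genes (median 0.605), mesenchymal markers (0.784), YAP/TEAD targets (0.819), WNT targets (1.79), glycolysis genes (0.521), trophoblast genes (0.966), cell cycle genes (−0.282) and leukocyte markers (−2.05). The leukocyte call was lost with no filter (adjusted p = 0.151) and the cell cycle call with quantile normalization (0.058). In all 9602 of 15227 genes were called, 4912 higher and 4690 lower. The numbers were 4538 and 5269 after quantile normalization and 5491 and 4079 after rescaling to the same total.

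**Figure D3:**
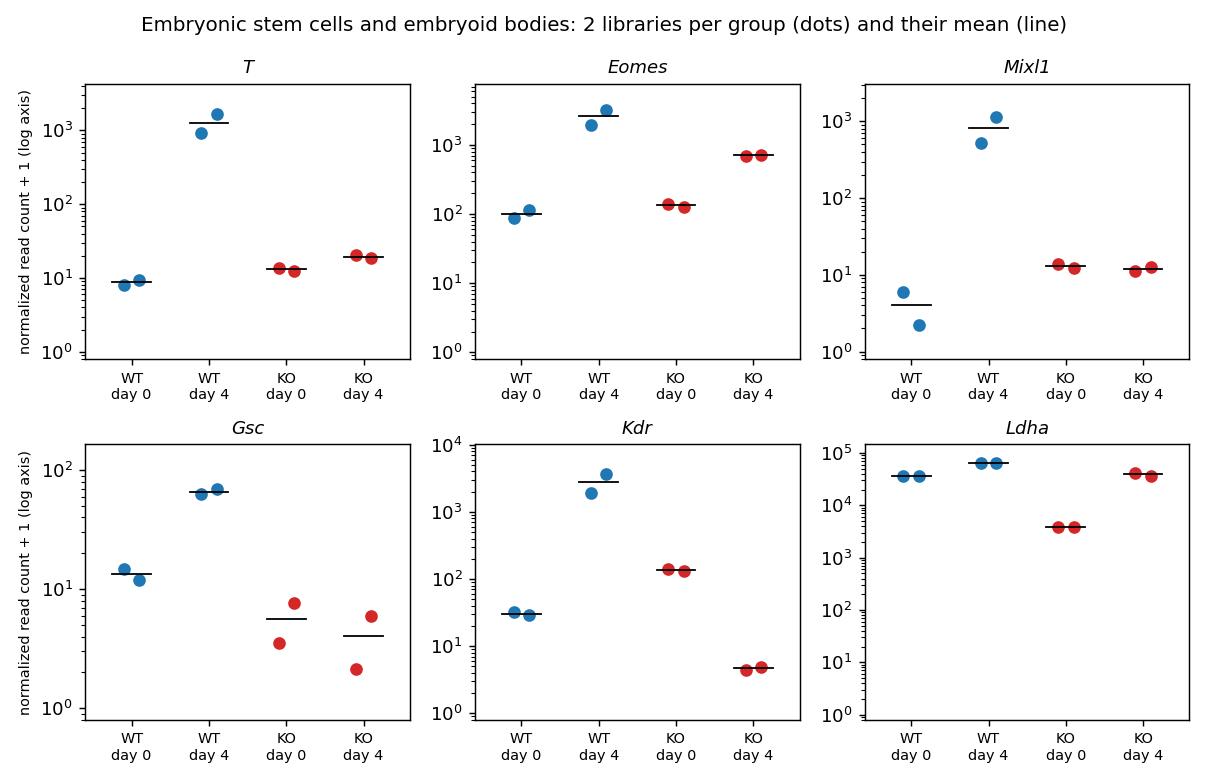
Deposited normalized counts plus 1 (log axis) of 6 genes in the 8 EB libraries, with 1 dot per library, blue for WT and red for labelled KO, and a black line at the mean of each group. T, Mixl1 and Kdr reached 1277, 825 and 2759 at day 4 in WT and 18.5, 11.01 and 3.67 in the cells labelled KO, and Ldha stood at 36930 in WT and 3851 in KO at day 0.

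In the EBs labelled KO, T stood at 12.1 ± 0.884 at day 0 and 18.5 ± 1.06 at day 4 (0.57 ± 0.29, adjusted p = 0.101). Mixl1 stood at 12.1 ± 0.884 and 11.01 ± 1.16 (−0.13 ± 0.44, adjusted p = 0.821) and Gsc at 4.62 ± 2.93 and 3.03 ± 2.68 (−0.55 ± 0.52, adjusted p = 0.374). None of these 3 changes passed the threshold. Eomes rose from 132 ± 7.25 to 706 ± 6.35 (2.41 ± 0.18, adjusted p = 6.84e-08). Ndufa4l2, a gene induced by low oxygen, was among the largest rises, from 9.28 ± 3.66 to 1903 ± 476 (7.56 ± 0.21, adjusted p = 3.07e-12). Fgf5 rose from 32.3 ± 8.45 to 1516 ± 194 and Otx2 from 2376 ± 80.7 to 11770 ± 79.0. Kdr fell from 136 ± 3.80 to 3.67 ± 0.387 (−4.87 ± 0.25, adjusted p = 1.17e-09) and the growth factor gene Csf1 from 524 to 7.27. Vim, encoding vimentin, fell from 3374 ± 111 to 489 ± 57.4, and Klf4 from 12140 ± 1180 to 578 ± 66.8.

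Naive pluripotency genes fell in 17 of 20 cases and rose in 3, and formative genes rose in 12 of 14 and fell in 2, both also adjusted over the list alone (medians −1.46 and 0.936, camera adjusted p = 9.72e-09 and 2.13e-06). Glycolysis genes rose in 19 of 20 cases and fell in none, also adjusted over the list alone (median 2.31, adjusted p = 1.84e-12), Ldha from 3851 ± 60.5 to 39480 ± 3840 among them. Mesenchymal markers fell in 12 of 15 and rose in 1 (median −0.948, adjusted p = 0.000494). YAP/TEAD targets fell in 8 of 12 and rose in 1 (median −1.07, adjusted p = 0.00181), both also adjusted over the list alone. EMT transcription factors, the study's list and not independent evidence, fell in 8 of 10 and rose in 1 (9 and 1 adjusted over the list alone, median −1.49, adjusted p = 0.0245), Zeb2 from 139 ± 7.32 to 51.8 ± 17.3. None of the list calls held with an estimated correlation (adjusted p from 0.122 to 0.556). The study's primitive streak genes, again not independent evidence, did not move as a list (3 higher and 4 lower of 22, 3 and 3 adjusted over the list alone, median −0.163, adjusted p = 0.829). Mesoderm genes did not either (3 higher and 9 lower of 22, also adjusted over the list alone, median −0.495, adjusted p = 0.183). Primitive and visceral endoderm genes went both ways (8 higher and 9 lower of 22, also adjusted over the list alone), and their median of 0.0162 differed in sign from their mean of −0.0852 and from the direction of the test (adjusted p = 0.829). Epithelial junction and keratin genes (median 0.898), cholesterol synthesis genes (0.273), cell cycle genes (−0.36), immediate early genes (−0.614) and Hox genes (−1.71) were called too. The cholesterol call was lost without KO day 0 replicate 1 (adjusted p = 0.0544). The immediate early call was lost with a mean of at least 100 (0.114), with the replicate block (0.0507) and without KO day 0 replicate 2 (0.0527) or KO day 4 replicate 2 (0.0702). The Hox call was lost with a pseudocount of 0.25 (0.0719), with the replicate block (0.0507) and without KO day 0 replicate 1 (0.0548), KO day 0 replicate 2 (0.0639) or KO day 4 replicate 1 (0.0896). Limma called 9134 genes, 4427 higher and 4707 lower, or 4598 and 4463 after rescaling to the same total.

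Tested as an interaction (KO minus WT), the day 4 change of T differed by −6.57 ± 0.41 on the log2 scale (adjusted p = 1.7e-08) and that of Mixl1 by −7.85 ± 0.63 (adjusted p = 1.98e-07). The difference for Eomes was −2.23 ± 0.26 (adjusted p = 7.09e-06) and for Gsc −2.86 ± 0.73 (adjusted p = 0.00438). Hand1 (−11.64 ± 0.62, adjusted p = 3.57e-09) and Kdr (−11.31 ± 0.36, adjusted p = 3.89e-11) were among the largest differences. Rreb1 rose in WT (0.54 ± 0.10, adjusted p = 0.000222) and fell in KO (−0.68 ± 0.10, adjusted p = 3.37e-05), with an interaction of −1.23 ± 0.14 (adjusted p = 5e-06). In the other direction stood Ndufa4l2 (7.62 ± 0.30, adjusted p = 3.02e-10).

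Among lists, mesoderm genes had a lower day 4 change in the cells labelled KO in 20 of 22 cases and a higher one in 1 (median interaction −4.28, camera adjusted p = 1.71e-08). The same held for primitive and visceral endoderm genes in 19 of 22 and 1 (−3.48, adjusted p = 4.84e-10) and for mesenchymal markers in 13 of 15 and 1 (−1.77, adjusted p = 2.48e-07). The change was lower for BMP/ID targets in 11 of 14 and none (−3.09, adjusted p = 3.56e-06), YAP/TEAD targets in 12 of 12 (−1.61, adjusted p = 2.48e-07) and Hox genes in 15 of 15 (−4.76, adjusted p = 9.13e-07). From the study, and not independent evidence, the primitive streak genes were lower in 21 of 22 with 1 higher (−4.51, adjusted p = 1.83e-08). EMT transcription factors, also from the study and not independent evidence, were lower in 10 of 10 (−4.93, adjusted p = 6.11e-07). Glycolysis genes were higher in 16 of 20 cases and lower in 1 (1.89, adjusted p = 2.68e-08). Nodal pathway genes, Lefty1 and Lefty2 among them, were higher in 8 of 13 with 3 lower (0.554, adjusted p = 0.0375). Definitive endoderm genes were lower in 10 of 14 with 2 higher (−3.29, adjusted p = 0.00183). Trophoblast genes were lower in 8 of 11 with 2 higher (−1.55, adjusted p = 0.00491). Each of these counts was the same adjusted over the list alone. Glycolysis genes were already lower in KO than in WT at day 0, and Hox genes and EMT transcription factors already higher, so their interactions include unlike starting levels. With a mean of at least 100 the Nodal (adjusted p = 0.0652), definitive endoderm (0.225, median −0.67) and trophoblast (0.0995) calls were lost. The Nodal call was also lost with quantile normalization (0.0528) and without WT day 4 replicate 1 (0.0924) or KO day 0 replicate 1 (0.0514). None of the 12 held with an estimated correlation (adjusted p from 0.122 to 0.286). The interaction was called for 8478 genes, 4124 higher and 4354 lower, or 4493 and 4002 after quantile normalization. Of 6032 genes called in both genotypes 4062 moved the same way and 1970 in opposite directions.

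**Figure D4:**
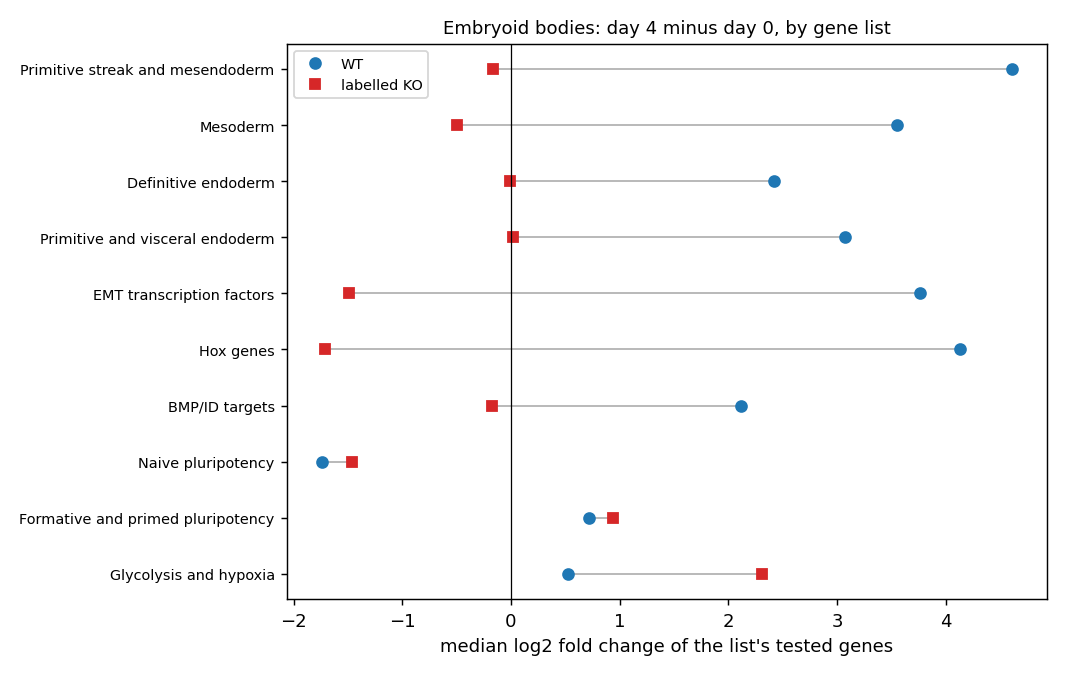
Median log2 fold change (x axis) of each gene list (y axis) for day 4 against day 0 in EBs, with blue circles for WT and red squares for labelled KO. Primitive streak genes lie at 4.61 in WT and −0.163 in KO, naive pluripotency genes at −1.74 and −1.46, and glycolysis genes at 0.521 and 2.31.

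At day 0, before differentiation, the stem cells labelled KO had a lower level of the Y-linked gene Eif2s3y (3064 ± 12.7 in WT and 4.46 ± 0.895 in KO, log2 fold change −9.14 ± 0.21 SE, adjusted p = 1.17e-12). The Y-linked genes Ddx3y (2014 ± 36.1 and 5.78 ± 1.42) and Uty (841 ± 9.75 and 3.19 ± 0.905) were lower too. The lysine breakdown gene Aass was at 422 ± 32.5 and 2.60 ± 2.32. Higher in KO were the elastic fibre gene Fbln5 (8.21 ± 0.383 and 401 ± 2.31, 5.45 ± 0.29, adjusted p = 1.84e-09), the collagen crosslinking gene Lox (14.4 ± 10.5 and 334 ± 30.9) and the cell death activator gene Hrk (156 ± 17.3 and 3256 ± 225). T (0.59 ± 0.29, adjusted p = 0.0839) and Eomes (0.40 ± 0.18, adjusted p = 0.0658) did not pass the threshold. Mixl1 was higher (1.85 ± 0.44, adjusted p = 0.00203), but not with edgeR (adjusted p = 0.134). Gsc was lower (−1.35 ± 0.52, adjusted p = 0.0323). This call was lost with quantile normalization (0.148), no filter (0.06), DESeq2 (0.0694) and without WT day 0 replicate 1 (0.139), WT day 0 replicate 2 (0.0647), WT day 4 replicate 1 (0.0671), WT day 4 replicate 2 (0.0674) or KO day 0 replicate 1 (0.257).

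Cholesterol synthesis genes were lower in all 19 cases (median −1.30, camera adjusted p = 4.57e-11), Hmgcs1 at 9106 ± 74.5 in WT and 2625 ± 43.3 in KO. Glycolysis genes were lower in 17 of 20 cases and higher in 2 (median −1.98, adjusted p = 1.82e-07), Bnip3 at 4324 ± 43.2 and 443 ± 14.0. Hox genes were higher in 11 of 15 and lower in none (median 2.51, adjusted p = 0.0115). Germ line and 2-cell-like genes were lower in 10 of 14 and higher in 3 (median −1.24, adjusted p = 0.0289), Dppa3 at 251 ± 7.15 and 39.5 ± 0.472. EMT transcription factors were higher in 10 of 10 (median 1.52, adjusted p = 0.0115), Snai1 at 37.1 ± 0.592 and 98.0 ± 11.5, in a list that came from the study and is not independent evidence. These counts were the same adjusted over the list alone, and none of the 5 calls held with an estimated correlation (adjusted p = 0.552). Naive pluripotency genes did not move as a list (11 higher and 6 lower of 20, median 0.226, adjusted p = 0.335). Limma called 10232 genes, 5161 higher and 5071 lower, or 4763 and 5449 after rescaling to the same total.

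At day 4, T (−5.97 ± 0.29, adjusted p = 5.98e-10), Mixl1 (−6.00 ± 0.44, adjusted p = 4.71e-08), Gsc (−4.21 ± 0.52, adjusted p = 8.6e-06) and Eomes (−1.83 ± 0.18, adjusted p = 1.17e-06) were lower in the cells labelled KO than in WT. Aplnr stood at 1483 ± 600 in WT and 0 in KO, at least 938-fold lower, Hand1 at 4299 ± 1360 and 3.32 ± 3.30, and Kdr at 2759 ± 1220 and 3.67 ± 0.387. The endoderm genes Sox17 (271 ± 41.8 and 2.54 ± 1.99) and Gata6 (524 ± 133 and 28.2 ± 4.98) and the N-cadherin gene Cdh2 (2131 ± 763 and 151 ± 11.4) were also lower. Hhip, which encodes a hedgehog-binding protein, was higher in KO (35.4 ± 12.0 and 908 ± 198, 4.67 ± 0.19, adjusted p = 1.55e-10). Also higher were Slc45a1 (30.4 ± 8.68 and 711 ± 81.9) and the naive pluripotency genes Nr0b1 (287 ± 14.8 and 2145 ± 390) and Esrrb (4110 ± 110 and 10560 ± 487).

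Primitive and visceral endoderm genes were lower in 21 of 22 cases and higher in none (median −3.81, camera adjusted p = 2.26e-14, and 0.0629 with an estimated correlation), and cholesterol synthesis genes lower in 18 of 19 and higher in none (median −1.21, adjusted p = 3.33e-11). Mesenchymal markers were lower in 13 of 15 and higher in none (median −1.47, adjusted p = 1.47e-07). BMP/ID targets were lower in 12 of 14 and higher in none (median −2.50, adjusted p = 8.12e-06). All 4 counts were the same adjusted over the list alone. Mesoderm genes were lower in 20 of 22 and higher in 1 (21 and 1 adjusted over the list alone, median −3.88, adjusted p = 3.33e-11). From the study, and not independent evidence, primitive streak genes were lower in 22 of 22 (median −3.94, adjusted p = 1.43e-11). EMT transcription factors, also from the study and not independent evidence, were lower in 8 of 10 with none higher (median −3.22, adjusted p = 2.15e-05). Both counts were the same adjusted over the list alone. Naive pluripotency genes were higher in 13 of 20 cases and lower in 5, also adjusted over the list alone (median 0.82, adjusted p = 0.00139). Definitive endoderm genes were lower in 10 of 14 and higher in 3, also adjusted over the list alone (median −2.62, adjusted p = 0.00101, and 0.0953 with a mean of at least 100). Lower as lists were also YAP/TEAD targets (median −1.08), trophoblast genes (−1.17), interferon response genes (−1.21), WNT targets (−1.84), germ line and 2-cell-like genes (−2.51) and Hox genes (−2.62). Leukocyte markers were higher in 6 of 6 cases, also adjusted over the list alone (median 1.19, adjusted p = 0.00463). The leukocyte call was lost with no filter (0.174), and the interferon (0.32) and WNT (0.0953) calls with a mean of at least 100. No list call held with an estimated correlation (adjusted p from 0.0629 to 0.266). In all 8555 genes were called, 4236 higher and 4319 lower. The numbers were 4816 and 4144 after quantile normalization and 3428 and 5331 after rescaling to the same total.

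The organoids had 1 library per condition, so their differences have no replicate check and describe these libraries alone. Without dox, Smad7 went from 321 under SB505124 to 1022 under TGFβ (log2 ratio 1.67, 95% counting interval 1.50 to 1.85). Snai1 (6.91 and 10.5, 0.54, −0.89 to 2.15) and Has2 (8.64 and 17.9, 0.97, −0.16 to 2.34) had intervals that included no change. With dox, TGFβ went with higher Smad7 (355 and 1710, 2.27, 2.12 to 2.42), Snai1 (3.72 and 70.2, 3.91, 2.94 to 5.91) and Has2 (28.3 and 166, 2.52, 2.03 to 3.11). The TGFβ target Pmepa1 went from 1818 to 15010 without dox and from 796 to 16130 with it. The median log2 ratio of 21 TGFβ/SMAD targets was 0.91 without dox and 0.999 with dox, each at percentile 100 of the matched random lists, with 9 and 10 of them at least 2-fold higher. The study's list of 17 fibrogenic genes, not independent evidence, had medians of 0.57 and 0.96, also at percentile 100. The interval of the first included 0 (−0.306 to 0.969). Interferon response genes moved apart, with a median of 2.08 without dox (percentile 100, 17 of 18 at least 2-fold higher, Ifit1 from 534 to 3764) and −0.96 with dox (percentile 0, 9 of 18 at least 2-fold lower). Mesenchymal markers had medians of 0.72 and 1.12 without and with dox (percentile 100). Lower under TGFβ were cell cycle genes (−0.503 and −0.134), immediate early genes (−0.473 and −0.435), glycolysis genes (−1 and −0.183) and cholesterol synthesis genes (−0.249 and −0.13), at percentiles from 0 to 1.2. The interval of the median included 0 for immediate early genes (−1.05 to 0.395 without dox, −1.01 to 0.203 with dox). It also did for cholesterol synthesis genes with dox (−0.197 to 0.0245). The fall of cell cycle genes ran against their rise in the PDA cells. Of the lists added after the data were seen, airway genes had medians of −0.833 and −1.02, gastric genes −0.816 and −1.23 and lung macrophage genes −2.44 and −0.902. Intervals included 0 for gastric genes (−2.37 to 0.143 without dox, −2.31 to 1.42 with dox) and for lung macrophage genes with dox (−4.18 to 1.09). The comparison without dox rests on the SB505124 library in which airway transcripts were more frequent. At least 2-fold higher under TGFβ were 479 genes without dox and 473 with dox, and 383 and 435 were at least 2-fold lower.

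**Figure D5:**
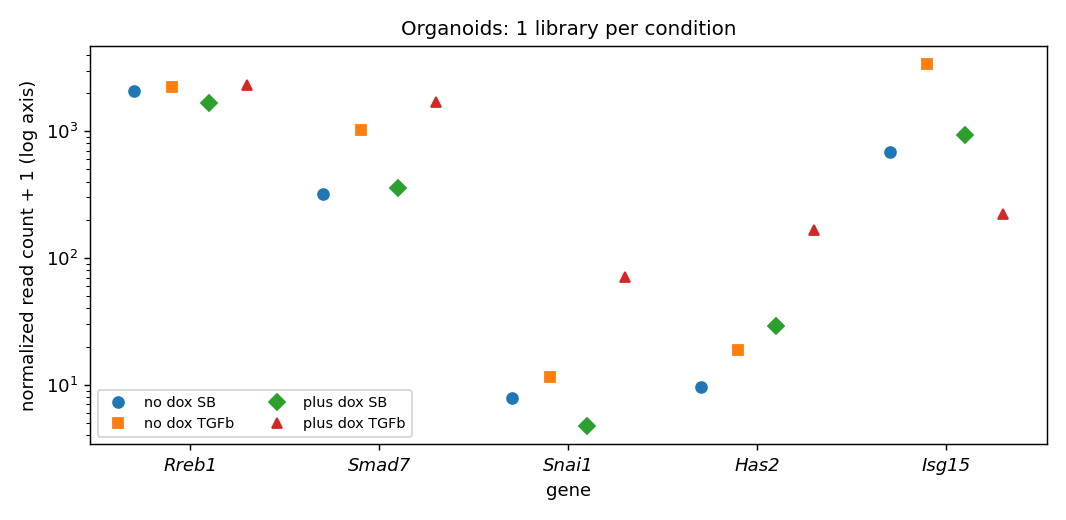
Deposited normalized counts plus 1 (log axis) of 5 genes in the 4 organoid libraries, with 1 marker per library for each combination of dox and treatment. Snai1 stands at 70.2 with dox under TGFβ and at 10.5 without dox under TGFβ, and Isg15 at 223 and 3377.

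With dox, ERK output genes were higher than without it, with a median log2 ratio of 0.72 under SB505124 and 0.81 under TGFβ over 20 genes, each at percentile 100. The ERK pathway gene Spry4 stood at 44.9 without and 388 with dox under SB505124, and the AP-1 gene Fosl1 at 8.64 and 190. Cell cycle genes had medians of 0.83 and 1.14 over 23 genes, and cholesterol synthesis genes 0.80 and 0.92 over 19, all at percentile 100. The 5 replication-dependent histone genes tested, listed beforehand as a quality check, had medians of −1.81 under SB505124 (percentile 0.18) and −0.711 under TGFβ (percentile 7.43). Without dox under SB505124, Hist1h2bc and Hist1h1c had 3012 and 3299 reads and the other members 30 or fewer. Whether RNA quality differed with dox cannot be told from these genes. Rrm2, a gene of nucleotide synthesis, stood at 1858 and 9896 and Ccne1 at 264 and 1125 under SB505124. Under TGFβ, dox went with higher Snai1 (2.63, 1.77 to 3.87), Has2 (3.15, 2.49 to 4.04) and Smad7 (0.74, 0.63 to 0.86). Glycolysis genes were lower with dox under SB505124 (median −1.17 over 18 genes, percentile 0), Bnip3 at 7515 and 849, and interferon genes under TGFβ (median −2.79 over 18, percentile 0). In the other treatment the medians were −0.211 for glycolysis genes (percentile 7.09) under TGFβ and 0.365 for interferon genes (percentile 98.35) under SB505124. Immediate early genes were higher with dox (0.782 and 0.838, percentile 100), the first with an interval that included 0 (−0.0398 to 1.57). The comparison under SB505124 rests on the library without dox in which airway transcripts were more frequent. In it the airway and lung macrophage lists, added after the data were seen, had medians of −1 and −2.85. Under TGFβ, a comparison without that library, their medians were −0.641 (percentile 0.46) and −0.0407 (percentile 60.07). The airway median was thus lower with dox under both treatments, but both intervals included 0 (−3.48 to 0.332 under SB505124, −1.86 to 0.186 under TGFβ). At least 2-fold higher with dox were 1066 genes under SB505124 and 1054 under TGFβ, and 1286 and 1291 were at least 2-fold lower.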

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

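The differences between genotypes given here came from interaction tests planned before the data were examined, and no test in this part was chosen only after the result was seen. Each was singled out because the same contrast, TGFβ against SB505124 or day 4 against day 0, gave different changes in WT and in the libraries labelled KO. Each value is the change in the cells labelled KO minus that in WT, on the log2 scale, called by limma or camera as in the report.

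In PDA cells 2886 genes passed the interaction test, or 1596 with the replicate number as a block. The count was 764 without WT TGFβ replicate 1, 827 without WT TGFβ replicate 2, 940 without KO SB replicate 1 and 1188 without KO SB replicate 2, so its size depends on which libraries enter. The lists with a lower TGFβ change in KO were TGFβ/SMAD targets (median −0.573), EMT transcription factors (−0.756), fibrogenic factors and matrix (−0.743) and immediate early genes (−0.658), and those with a higher change were cell cycle genes (0.361) and cholesterol synthesis genes (0.479). Under SB505124 the cell cycle genes were already lower in KO than in WT and the immediate early genes already higher, so these differences include unlike starting levels. None of the 6 list calls held with an estimated correlation (adjusted p from 0.135 to 0.315), and that of the EMT transcription factors was also lost without WT SB replicate 2 (adjusted p = 0.0799) or KO TGFβ replicate 1 (0.0513). The lowest single fitted differences were those of Arc (−5.60), Lancl3 (−4.38), Aldh1l2 (−3.37), Cish (−3.30), Stamos (−2.99) and Ihh (−2.97), among genes with a mean of at least 50. Ihh, a hedgehog ligand gene, rose from 7.32 to 126 in WT and from 679 to 1344 in KO. Stamos overlaps other transcription and the libraries do not mark strand, so its reads are uncertain. The largest positive fitted differences were those of Ces1g (2.92), Frmpd1 (1.96), Ces1f (1.95), Rgs2 (1.93), Aqp11 (1.90) and Cdcp1 (1.87). Those of Ces1g, Ces1f and Cdcp1 rest on groups at or near 0, so the fitted values depend on the pseudocount and are no bounds, and the Ces1 genes share reads. Ces1f was not called by edgeR (adjusted p = 0.105) or DESeq2 (0.155), Cdcp1 was not called by DESeq2 (0.0736), and its sign turned with a pseudocount of 8 (−0.0026, adjusted p = 0.994). Rreb1 responded less in KO (−1.20).

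In EBs 8478 genes passed the interaction test. The lists with a lower day 4 change in the cells labelled KO were EMT transcription factors (median −4.93), Hox genes (−4.76), primitive streak and mesendoderm (−4.51), mesoderm (−4.28), primitive and visceral endoderm (−3.48), definitive endoderm (−3.29), BMP/ID targets (−3.09), mesenchymal markers (−1.77), YAP/TEAD targets (−1.61) and trophoblast (−1.55). Glycolysis and hypoxia genes (1.89) and Nodal pathway genes (0.554) had a higher change. At day 0 glycolysis genes were already lower in KO than in WT, and Hox genes and EMT transcription factors already higher. The differences for these lists therefore include unlike starting levels. With a mean of at least 100 the definitive endoderm (median −0.67, adjusted p = 0.225), trophoblast (−0.97, adjusted p = 0.0995) and Nodal (adjusted p = 0.0652) calls were lost. The Nodal call was also lost with quantile normalization (0.0528) and without WT day 4 replicate 1 (adjusted p = 0.0924) or KO day 0 replicate 1 (0.0514), and no list call held with an estimated correlation (adjusted p from 0.122 to 0.286). Among genes set beforehand, the differences were −6.57 for T, −2.23 for Eomes, −2.86 for Gsc, −7.85 for Mixl1 and −1.23 for Rreb1. The lowest fitted values, among genes with a mean of at least 50, were those of Hand1 (−11.64), Kdr (−11.31), Aplnr (−10.96), the netrin receptor gene Unc5c (−10.79) and the cadherin genes Pcdh7 (−10.70) and Cdh11 (−10.07). Aplnr, with groups at 0, was not called by edgeR (adjusted p = 0.0558), and its fitted value is no bound. Hand1, Kdr, Unc5c, Pcdh7 and Cdh11 also had groups near 0, such as 2 reads of Unc5c in KO at day 4, so their fitted values depend on the pseudocount. The calls of these 5 genes held with pseudocounts of 0.25 and 8, edgeR and DESeq2. Ndufa4l2 (7.62), Aass (5.54), the synuclein gene Sncb (4.89), Bcl11a (4.88) and Sh2d5 (4.57) were among the largest positive differences, with Aass (6 reads) and Sncb (10 reads) near 0 in KO at day 0.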

How the results depend on the processing

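Leaving out X-linked and Y-linked genes from the EB table, and airway and lung macrophage genes from the organoid table, was chosen only after the result was seen, and the other alternatives were planned. Leaving out single libraries moved the PDA counts most, where the lone library left in a group was assumed to vary like the other groups. The number of called genes then ran from 2254 to 5183 for the TGFβ response in WT, from 2956 to 5931 in KO, from 764 to 3881 for the interaction, from 5512 to 7689 for KO against WT under SB505124 and from 3212 to 6148 under TGFβ. The lowest counts of the WT response, the interaction and KO against WT under TGFβ came without WT TGFβ replicate 1, that of the KO response without KO SB replicate 1, and the replicates of the 4 groups differed unequally (chi-square per degree of freedom 48.5 in WT SB, 1.94 in WT TGFβ, 2.95 in KO SB and 39.2 in KO TGFβ) while sharing an estimate of the spread. The difference in the size of the TGFβ response between genotypes ran from −0.0163 to 0.0859 and turned its sign without WT SB replicate 2. In EBs the counts ran from 7842 to 9990 for the day 4 change in WT, from 7626 to 8847 in KO, from 7108 to 8430 for the interaction, from 8663 to 10564 for KO against WT at day 0 and from 6904 to 8452 at day 4. The difference of Rreb1 at day 4 ran from −0.0201 to 0.325 and was called without KO day 4 replicate 2. With the replicate number as a block the PDA interaction count was 1596, the other 10 counts stayed within 1.5 times, 15 gene calls and 2 list calls were lost and 1 gene call was gained. Same-numbered libraries deviated at most weakly in the same direction (correlations from −0.51 to 0.14 in PDA cells and from −0.033 to 0.091 in EBs), so the numbers give no evidence of pairing. The −0.51 lay between WT SB and KO TGFβ, so libraries of different number deviated together in these groups. A block by replicate number does not take up such a shared deviation, and its source was not tested. The interaction of Cdcp1 turned from 1.87 to −0.0026 with a pseudocount of 8, which by its construction damps differences between groups near 0. In the organoids a mean of at least 50, which tests fewer genes, lowered the counts of genes at least 2-fold higher and lower under TGFβ to 308 and 225 without dox and to 279 and 228 with dox, and a pseudocount of 8 lowered the last to 280. For the other changes the cause was not tested. All 11 counts of called genes stayed within 1.5 times with edgeR, DESeq2, quantile normalization, rescaling to the same total and robust moderation. Of the list calls, 98 were lost with an estimated correlation. Those of TGFβ/SMAD targets held in the WT and mean TGFβ responses. In the day 4 change of WT EBs, those of naive pluripotency genes and of primitive and visceral endoderm genes held. No other call of a list written beforehand did. Of the values for named genes, edgeR ended 11 calls and DESeq2 26, and leaving out single libraries ended 198 and added 21 against 8285 on the same side. Without X-linked and Y-linked genes the 5 EB counts stayed within 1.5 times (from 8197 to 9904), as did the 8 organoid counts without airway and lung macrophage genes. These steps took out few genes (14696 EB genes stayed, against 15227 in the main fit), so the counts could hardly move that far. They do not show whether the Y-linked or airway patterns affect the other differences. Depth limits genes near the floor. Among the PDA and EB groups it does so most in KO SB, where 3 counts equal a value of 1.89. In the single organoid libraries 3 counts equal values from 2.232 to 3.395.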

Other observations

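The tests in this part were chosen only after the result was seen, except those of X-linked genes and of gains or losses of other whole chromosomes, and the lists named here as added were written after the data were seen.

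In the PDA cells labelled KO, an added list of 13 gastric and mucous epithelium genes was higher than in WT in 10 cases and lower in 2 under SB505124 (median log2 fold change 1.30) and under TGFβ (1.61). The counts were the same adjusted over the list alone. Chosen after their values were seen, the gastrokine gene Gkn1 stood at 54.9 ± 8.81 in WT and 1554 ± 21.1 in KO under SB505124. The trefoil factor gene Tff1 stood at 102 ± 30.6 and 1297 ± 30.1 (SD, n = 2). In EBs an added list of 21 amino acid and integrated stress response genes was higher in the cells labelled KO in 19 cases at day 0 (median 1.76) and in 20 at day 4 (median 1.53). Neither call held with an estimated correlation (adjusted p = 0.154 and 0.105). Chac1, which encodes an enzyme that degrades glutathione, stood at 800.3 ± 13.2 in WT and 3630 ± 69.7 in KO at day 0, and Trib3, a target of the stress regulator ATF4, at 1380 ± 19.7 and 5863 ± 386.

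An added list of unfolded protein response genes was lower under TGFβ than under SB505124 in PDA cells, in 21 of 21 cases in WT (median −1.37) and in 20 of 21 in the cells labelled KO (21 adjusted over the list alone, median −2.53). The larger fall in KO started from a higher level, since under SB505124 the list was higher in KO than in WT in 17 of 21 cases and lower in 1, also adjusted over the list alone (median 0.766), Hspa5 at 223000 in WT and 625600 in KO. Under TGFβ the genotypes differed by a median of −0.0151. Scaling distorted by a few abundant genes was argued against by the medians without Hspa5 after quantile normalization, −1.34 (interval −1.87 to −1.04) in WT and −2.18 (−2.99 to −1.55) in KO. The shallower KO SB library could bear on the fall in KO alone, and there it was argued against by the median without it, −2.51. A change that these treatments bring in every pancreatic epithelial culture was argued against by the organoid medians of −0.0599 without dox and −0.00505 with dox. A stress of these PDA cultures during the longer SB505124 treatment may lie behind the pattern, but the design ties the inhibitor to its time, and this stays open and untested.

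Y-linked genes were near 0 in the EB libraries labelled KO, where the deposited values of 11 genes summed to 19.5, 18.2, 32.8 and 31.5, against 6521, 6457, 5193 and 5117 in WT. A line with 2 active X chromosomes was argued against by the change of X-linked genes less that of autosomal genes at day 0, 0.0817 (interval −0.00218 to 0.167). Gains or losses of other whole chromosomes were argued against by the largest autosomal shift shared by both days, 0.0457 on chromosome 12. That shift does not bear on why Y-linked genes were near 0. A swap of labels between the genotypes cannot be told apart from a true difference of the lines, since finding all 8 libraries on the side of their label only restates the pattern. Loss of the Y chromosome in the line labelled KO may lie behind the pattern too, but this stays open and untested, and whether it affects the other differences between these lines was not tested. Part of the reads of Uba1y may come from its X-linked copy.

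Airway transcripts in the organoid library without dox under SB505124 made up 86043 reads over 16 added list genes, 2.52 times the rate in the other 3 libraries together. The lower counting limit of that ratio was 2.5. The list was written after these reads were seen and the reads are many, so this limit is no independent test of counting noise. Cells or RNA from airway tissue are a candidate source, and 8 of the list genes had at least 10 reads and a lower limit over 2, but this stays open, since 12 of the 16 genes also had at least 10 reads in each of the other 3 libraries. The other 4 were nearly confined to this library, with 170 reads of Scgb1a1 against 2 in the other 3 together, and 113 of Bpifa1, 27 of Scgb3a2 and 13 of Bpifb1 against 0. The most abundant were Cyp2f2, at 34600, 21000, 3107 and 1348, and Sftpd, at 26130, 20200, 8871 and 5582 (without dox under SB505124 and TGFβ, then with dox under SB505124 and TGFβ). Both were thus also high without dox under TGFβ, and the ratio to the other 3 libraries joins unlike libraries. The median of 7 added lung macrophage and antigen presentation genes, TGFβ against SB505124 without dox, was −2.44, and Chil3, a macrophage gene, had 219 reads in the library without dox under SB505124 and 0 in the other 3. Which cells gave these reads cannot be told apart, as the labels give only pancreatic epithelial cells and each condition has 1 library.

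In PDA cells the median change of genes on chromosome 13, which holds Rreb1, taken relative to that of all autosomes, was −0.402 for KO against WT under SB505124 (interval −0.479 to −0.336) and −0.346 under TGFβ (−0.377 to −0.318). It was 0.26 and 0.257 on chromosome 6, 0.241 and 0.226 on chromosome 1, and 0.201 and 0.222 on chromosome 8. These medians do not tell a difference in karyotype between the lines from other causes, and such a difference would bear on the values for KO against WT. In EBs chromosome 18 stood at 0.173 at day 0 and 0.0144 at day 4. In the organoids the amino acid and integrated stress response list had medians of −0.813 and −0.467 for TGFβ against SB505124 without and with dox, and of 1.41 and 1.67 for dox against no dox under SB505124 and TGFβ.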
